A study of Mus musculus with 18 samples.

How the data were processed

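Total RNA of sorted mTECs was purified on an automated Maxwell 16 instrument (Promega) and made into libraries with the SMART-seq v4 Ultra Low Input kit, per the labels, which name triplicates, the strain and the genotype of each group. The 18 libraries formed 6 groups of 3. Per the file headers the reads were trimmed single reads with Ion Torrent barcodes. The column names place the 12 Aire and Fezf2 libraries in one sequencing run and the 6 Chd4 libraries in another. The submitters' processing notes name DESeq2 without a version and the builds mm10 and GRCm38. Which of the deposited columns DESeq2 gave, the aligner, the handling of strand and of reads that match several places, and the deleted exons are not given in the sources used here. Counts of near-identical genes (Sprr2a, Xlr3 and Xlr4, Dcpp, Hba and Reg3 families) and of antisense genes (Dgkeos, Slmapos2) are therefore uncertain.

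The authors deposited 3 tables with counts, 1 for each targeted gene, whose columns hold the total exon reads of each gene in each library, per the file headers. Other deposited columns are annotation (gene ID, position, exon length). The Aire and Fezf2 tables also hold a score, the signed fold change of the authors' EDGE test with tagwise dispersions, and the p values of that test corrected for false discovery, per the file headers. A summary table of the authors gives the log2 of each group's mean RPKM, pooled over the 3 libraries, and p and q values of their comparisons. Only the counts entered the tests here, and a total of 216 further per-library columns over the 3 tables were not used. The columns name a group and a barcode but no replicate number, so libraries were mapped to groups only, and A, B and C follow barcode order.

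The Aire and Fezf2 tables hold 49585 genes and that of Chd4 holds 21969, with 21875 gene IDs in both, so levels in the Chd4 libraries and in the others come from different annotations. Starts in the tables were 0-based and were raised by 1. After that 91.4% of the genes of the Aire and Fezf2 tables found in a GRCm38 annotation had its start and end, and 74.0% of those of the Chd4 table, while 99.9% overlapped its position in either. Fezf2 spans 12342094 to 12348189 in that annotation. For the Chd4 data, 25 symbols that had become dates were restored from their gene IDs. Tulp2 is given in the Chd4 table with a suffix. Exon reads per library ranged from 3571570 to 17220157, mitochondrial genes took 1.24 to 2.5% of them and the 10 highest genes 7.91 to 11.31%.

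Each comparison was fitted on its 6 libraries with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter and quasi-likelihood F tests. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower. The biological coefficient of variation was 0.183 for Aire, 0.279 for Fezf2, 0.149 for Chd4 and 0.28 for the comparison of the WT groups. The standard error of a log2 fold change was taken as its size divided by the square root of F. Where a group had 0 reads, a bound on the fold was computed with 3 reads over the group, and where it had 1 to 3 reads the ratio of reads with an exact conditional (binomial) 95% interval, which covers counting error only. Group values are means and SD over the libraries, n = 3 per group. What the labels do not state about how independent the triplicates are is unknown, and p values measure the spread between these libraries. The WT groups were compared with the WT for Aire as the control. Non-overlap counts are genes with all 3 libraries of one group above all 3 of the other.

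For gene lists, 36 lists of known genes, chosen from general knowledge of tissues, mTEC subtypes and pathways, were written before the data were examined. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjusted p over the lists tested, and counts of members past the threshold are given over all genes and adjusted over the list alone. Lists with fewer than 3 tested members were not tested. Lists can share genes, and most of the Aire-dependent and Fezf2-dependent examples are also on other lists. List results and the totals of lists passed are therefore not independent. Shared calls were tested with one-sided Fisher's exact tests among genes tested in both comparisons, adjusted over 12 tests, of which the 6 for opposite directions were added after the files were examined. Differences between effects were tested as interaction contrasts in an edgeR fit of all 18 libraries. Genes detected were counted after thinning the 6 libraries of a comparison to equal depth and compared by exact permutation of the 3 against 3 labels. The sex of each animal was inferred from 4 Y-linked genes, male above 50 CPM, a threshold chosen after the values were seen. Xist is absent from the Chd4 table.

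Named genes followed a rule fixed with the design. It took Aire, Fezf2 and Chd4 in every comparison, and in each direction the 8 genes with the largest change among those past the threshold with a mean of at least 2 log2 CPM and no overlap between the groups. It passed over predicted genes (Gm and a number, names ending in Rik), mitochondrial genes, antigen receptor segments and clone names (AC, AL or CT and digits). It further took up to 4 members per list with the smallest adjusted p, 6 genes per direction for overlaps and 5 per direction for differences, and some of them are not reported here. Lists were described in full where the camera test passed or at least 3 members were past the threshold.

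The tests were checked on simulated data with the dispersions and means of each comparison and 200 changed genes. At a 4-fold change 90.9% were recovered for Aire, 75.8% for Fezf2, 92.4% for Chd4 and 78.8% for the WT groups. At a 2-fold change 50.7%, 14.9%, 62.7% and 25.4% were recovered, and of the calls 4.8%, 7.7%, 6.7% and 2.8% were false. At a 1.5-fold change 0% were recovered for Fezf2. Genes were simulated independently of each other, with no shift shared across the genes of a library. These shares therefore do not cover a library that stands apart, as library B of the WT for Fezf2 does. The group values of the deposited summary table could be derived from the count tables for nearly all genes of Chd4, but not exactly for Aire and Fezf2, so the following counts may not rest on the same input. That table called 2323 genes at q under 0.05 for Aire (809 higher, 1514 lower), of which 727 and 1252 were also called here in the same direction. For Fezf2 it called 1245 (621 and 624, of which 376 and 348), and for Chd4 4058 (2049 and 2009, of which 1975 and 1811), and 0 were called here in the opposite direction.

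The alternatives tried were DESeq2 size factors in edgeR (RLE), the DESeq2 1.42.0 Wald test, no filter, a filter at 1 CPM in 3 libraries, one fit of all 18 libraries, an added fold threshold of 2, a sex covariate, and leaving out each library in turn. For lists they were an estimated correlation, fry, RLE and no filter. For overlaps they were an adjusted p of 0.01, DESeq2 calls and a fold threshold, for correlations a level of at least 2 log2 CPM and DESeq2, and for genes detected 3 and 10 reads. Added after seeing the data were limma voom with sample quality weights, thinning to equal depth, leaving out libraries for the lists, and leaving out library B of the WT for Fezf2 for overlaps, correlations and differences. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.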

Results

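RNA-seq was measured in sorted mouse medullary thymic epithelial cells (mTECs), the thymic cells that transcribe genes of many peripheral tissues and present them to developing T cells. The 18 libraries fell into 6 groups of 3. These were mice labelled Aire KO with a wild-type (WT) control group of their own, mice labelled Fezf2 KO with a separate WT group, and Chd4 conditional knockout (cKO) mice with a control group. The column names of the counts call the Fezf2 KO libraries Fezf2cKO and their controls only ctl. The sample labels and the column names thus differ on whether the Fezf2 knockout was conditional, and the labels are used below. The Aire and Fezf2 groups were C57BL/6. The Chd4 groups were C57BL/6x129P2 and carried floxed Chd4, with Foxn1-Cre in the cKO, a recombinase active in thymic epithelium. Below, the control groups are called the WT for Aire, the WT for Fezf2 and the Chd4 control, and the 3 libraries of a group are named A, B and C. Exon reads per library ranged from 4376914 to 4834213 in the WT for Aire and from 4374935 to 4858250 in the group labelled Aire KO. They ranged from 3935102 to 4501080 in the WT for Fezf2, from 4377169 to 5928985 in the Fezf2 KO and from 3571570 to 4178824 in the Chd4 control. The Chd4 cKO libraries A, B and C held 6946014, 17220157 and 4713401. A gene with 0 reads in a library could still stand at up to 0.174 CPM in the deepest library and 0.84 CPM in the shallowest, taking 3 reads as the floor. Group values are means ± SD of TMM-normalised CPM over the 3 libraries of each group, and fold changes are log2 of the second group over its control.

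Fezf2 and Chd4 transcripts were lower in the groups that the labels name for them, and the Aire transcript was higher in the group labelled Aire KO. Fezf2, a zinc finger transcription factor of mTECs (ENSMUSG00000021743, protein coding, GRCm38 chromosome 14, 12341892 to 12345865), stood at 652.6, 734.8 and 569.9 CPM in the WT for Fezf2 and at 9.09, 8.44 and 23.4 CPM in the Fezf2 KO. Chd4, the helicase of the NuRD chromatin remodelling complex (ENSMUSG00000063870, protein coding, chromosome 6, 125095981 to 125130591), stood at 55.42, 66.54 and 58.86 CPM in its control and at 24.58, 27.47 and 30.19 CPM in the cKO. Aire, the transcriptional regulator that promotes tissue-restricted genes in mTECs (ENSMUSG00000000731, protein coding, chromosome 10, 78030022 to 78043610), stood at 1942, 1810 and 2302 CPM in its WT and at 3737, 4088 and 3997 CPM in the libraries labelled Aire KO. The deleted part of Aire is not given in the sources used here, so a count over the whole gene does not check that label. Directions below are therefore given for the libraries labelled Aire KO.

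**Figure D1:**
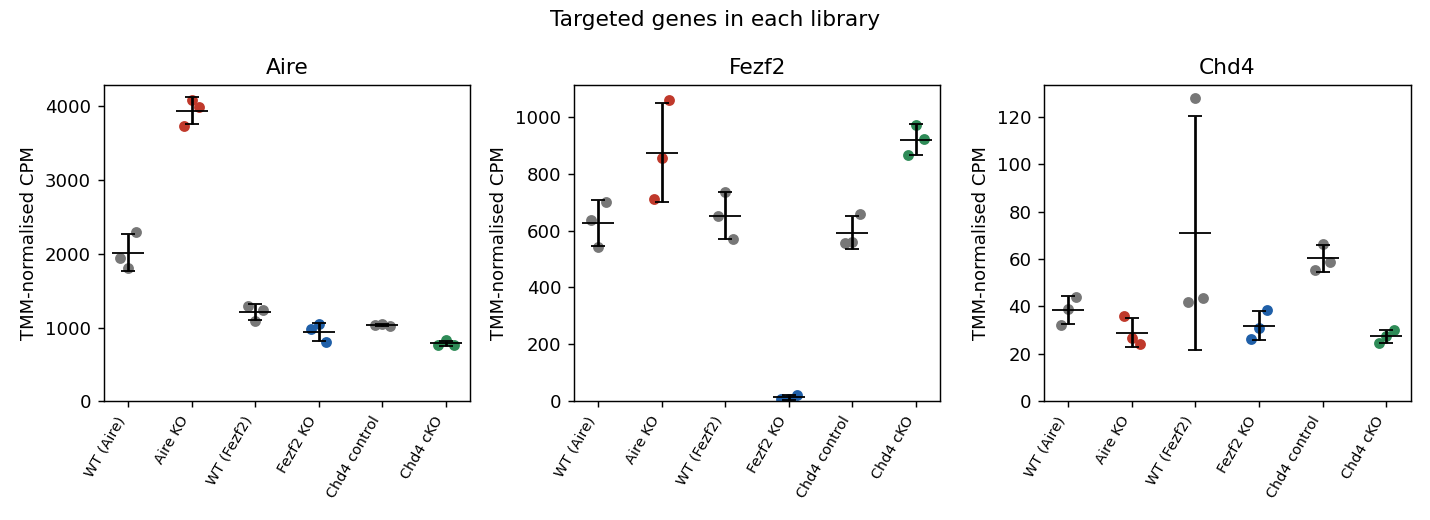
TMM-normalised CPM of Aire, Fezf2 and Chd4 in each of the 18 libraries (points), with the mean and SD of each group of 3 (bars). Aire stood between 3737 and 4088 CPM in the libraries labelled Aire KO and between 1810 and 2302 CPM in their WT.

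The comparison of the libraries labelled Aire KO with their WT asked which mTEC transcripts depend on Aire. Most lists of peripheral tissue genes were lower, with many genes left without a single read, while the testis list did not pass and MHC class II genes were modestly higher. These list calls were lost with an estimated correlation, where the lowest adjusted p was 0.0505 and that of MHC class II 0.16. Retnla, a resistin-like hormone, had 62.0 ± 11.2 CPM in the WT and 0 reads in the libraries labelled Aire KO, at least 272-fold lower (adjusted p = 3.51e-07). Ppy, pancreatic polypeptide, had 35.8 ± 11.4 CPM and 0 reads, at least 156-fold lower (adjusted p = 3.8e-06). Of 14949 genes tested, 1401 were lower and 856 higher, together 15.1%, and 1083 of the lower but 186 of the higher genes changed at least 2-fold. The median change was 4.08-fold among the lower genes, of which 123 had 0 reads, and 1.61-fold among the higher genes. The lower genes were expressed at a median of 3.39 log2 CPM, the higher genes at 6.52 and all tested genes at 4.58. In 4804 genes (32.1%) the groups of libraries did not overlap, where chance gives 10% and the WT for Fezf2 against the WT for Aire gave 20.4%. Over the same number of reads, 18953 ± 163 genes were detected in the libraries labelled Aire KO and 21420 ± 377 in the WT, a difference of -2467 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give).

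Other genes with the largest decreases had 0 reads in all 3 libraries labelled Aire KO. These were Prss29, a serine protease (at least 215-fold lower), Gstm3, a glutathione transferase (at least 151-fold), and Bpifb9b (at least 145-fold). Lefty2, a secreted inhibitor of nodal signalling, was at least 130-fold lower, Calb2, the calcium-binding protein calretinin, at least 110-fold, and Cyp1a2, a liver cytochrome P450, at least 101-fold. Their adjusted p values lay between 1.39e-06 and 2.11e-05. Among the genes with the largest increases, Acot12, an acetyl-CoA thioesterase, rose from 5.78 ± 1.61 to 29.3 ± 0.466 CPM (log2 fold change 2.33, SE 0.26, adjusted p = 5.65e-05). The olfactory receptor gene Olfr1136 rose from 9.42 ± 2.96 to 44.0 ± 5.36 CPM (2.23, SE 0.23, adjusted p = 3.83e-05). Slmapos2, annotated opposite to Slmap, rose from 44.3 ± 14.2 to 200 ± 34.6 CPM (2.18, SE 0.20, adjusted p = 1.34e-05), although reads of a gene and its antisense partner may be mixed. Rgr, a retinal opsin-like receptor, St6galnac3, a sialyltransferase, and Gria1, a glutamate receptor subunit, rose by log2 fold changes of 2.54, 2.08 and 2.05. Xlr4b, one of a family of near-identical X-linked genes, rose by 3.15 (adjusted p = 0.00578) and did not pass with sample quality weights (adjusted p = 0.0897, the highest over its settings, the lowest being 1.43e-10). RP23-361B11.3 rose by 2.01 (adjusted p = 0.0154), a call that was lost without WT for Aire A or C or without Aire KO A or B, with adjusted p of at most 0.0682.

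All 11 tested pancreas genes fell, with a median log2 fold change of -3.68 (camera adjusted p = 1.34e-13). Ins2, insulin, fell from 448 reads to 1, a ratio of 418 with a counting interval of 74.6 to 16500. Cel, a pancreatic lipase, and Sst, somatostatin, had 0 reads and were at least 97.3-fold and 75.2-fold lower. All 8 lung and airway genes fell (median -1.80, adjusted p = 1.12e-07). Sftpd, surfactant protein D, went from 54.0 ± 11.5 to 14.5 ± 6.34 CPM and Bpifa1, an airway secretory protein, from 267 ± 37.0 to 81.7 ± 41.2 CPM. Of 16 liver genes 9 fell and 0 rose by edgeR (11 and 0 adjusted over the list alone; median -2.10, adjusted p = 3.06e-07), among them Fgg, a fibrinogen chain, from 26.2 ± 7.13 to 0.611 ± 0.359 CPM. Apoa1, the apolipoprotein of high-density lipoprotein, went from 102 ± 26.1 to 26.4 ± 2.72 CPM. Of 15 intestine genes 10 fell and 0 rose, by all genes or over the list alone (median -1.55, adjusted p = 2.98e-06). Tff3, a mucosal trefoil peptide, went from 61.4 ± 7.29 to 3.86 ± 1.14 CPM, Reg3b, an antimicrobial lectin, from 58.4 ± 13.9 to 3.15 ± 3.88 CPM, and its close relative Reg3g from 1552 ± 458 to 529 ± 73.4 CPM. The tissue lists lost their calls with an estimated correlation, with adjusted p = 0.0505 for pancreas, lung and intestine and 0.0781 for liver.

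Of 13 brain genes 8 fell and 1 rose (10 and 2 adjusted over the list alone; median -1.69, adjusted p = 2.71e-05, and adjusted p = 0.0799 with an estimated correlation). Pcp4, a Purkinje cell protein, went from 40.9 ± 7.13 to 2.87 ± 0.892 CPM and Calb1, calbindin, from 36.1 ± 6.24 to 9.48 ± 2.85 CPM. Of 9 salivary gland and milk genes 7 fell and 1 rose, by all genes or over the list alone (median -5.80, or -4.73 with genes at 0 reads set to their bound; adjusted p = 5.73e-06, and 0.0505 with an estimated correlation). The milk casein Csn1s2a went from 22.7 ± 6.08 to 0.380 ± 0.125 CPM, while the near-identical Dcpp1, Dcpp2 and Dcpp3 may share reads. Of 8 pituitary and thyroid genes 4 fell and 0 rose (4 and 2 adjusted over the list alone; median -1.55, adjusted p = 0.0136, and 0.165 with an estimated correlation). Pomc, the precursor of corticotropin, went from 56.2 ± 11.5 to 3.46 ± 1.40 CPM, and the hormone genes Avp and Oxt had 0 reads and were at least 45.4-fold and 41.6-fold lower. Of 6 kidney genes 3 fell and 0 rose, by all genes or over the list alone (adjusted p = 0.00249, and 0.117 with an estimated correlation), including Slc12a3, a salt transporter with 0 reads and at least 28.9-fold lower. Of 7 eye genes 3 fell and 0 rose (4 and 0 adjusted over the list alone; adjusted p = 0.0113, and 0.173 with an estimated correlation), led by the lens crystallin Cryaa from 46.6 ± 8.59 to 0.625 ± 0.376 CPM. The eye call was lost without WT for Aire A (adjusted p = 0.09, with a range of 0.00214 to 0.173 over its settings). The list of genes often cited as Aire-dependent had 7 lower and 1 higher of 9 (8 and 1 adjusted over the list alone, median -3.99, adjusted p = 1.05e-07, and 0.0505 with an estimated correlation). Members such as Ins2, Ppy, Pcp4 and Tff3 are also on the pancreas, brain or intestine lists, so this list is not separate from those.

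Genes of other mTEC-derived cell types moved too. Of 8 microfold cell genes 5 fell and 0 rose (6 and 0 adjusted over the list alone; median -1.0, adjusted p = 3.14e-05, and 0.243 with an estimated correlation). The chemokine Ccl20 went from 341 ± 67.7 to 111 ± 20.5 CPM and Gp2, an uptake receptor for bacteria, from 298 ± 77.6 to 84.8 ± 29.0 CPM. Of 17 keratinocyte genes 5 fell and 0 rose, by all genes or over the list alone (median -0.41, adjusted p = 0.0252, and 0.465 with an estimated correlation), led by Casp14, a protease of cornification (-3.20, SE 0.66, adjusted p = 0.00462). That call was lost without WT for Aire B (adjusted p = 0.0907) or Aire KO A (0.182), with a range of 0.00187 to 0.465 over its settings. Between the WT groups the keratinocyte list had a median of 0.88, larger than the fall here. Of 13 muscle genes 5 fell and 0 rose (6 and 0 adjusted over the list alone; median -0.80, adjusted p = 0.0287, and 0.182 with an estimated correlation), led by the embryonic myosin Myh3 with 272 reads against 3, a ratio of 84.5 with a counting interval of 28.6 to 413. It was lost without WT for Aire B (adjusted p = 0.0563) or Aire KO A (0.0739), with a range of 0.00626 to 0.182.

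MHC class II and interferon-stimulated genes moved in opposite directions. Of 11 MHC class II genes 8 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.39, adjusted p = 2.23e-05, and 0.16 with an estimated correlation). H2-Ob, a class II loading modulator, rose from 140 ± 5.98 to 241 ± 35.8 CPM and Ciita, the class II transactivator, from 233 ± 23.0 to 335 ± 25.8 CPM. Of 16 interferon-stimulated genes 8 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.58, adjusted p = 4.14e-05, and 0.212 with an estimated correlation), with Ifit3 going from 67.2 ± 8.71 to 20.9 ± 5.65 CPM and Isg15 from 75.7 ± 14.0 to 26.6 ± 4.60 CPM. Of 12 mTEC maturation genes 4 rose and 3 fell (4 and 4 adjusted over the list alone; median -0.02, adjusted p = 0.971). The chemokines Ccl22 and Ccl17 fell from 856 ± 172 to 175 ± 89.4 CPM and by a log2 fold change of -1.92, while Hdc, histidine decarboxylase, rose by 0.72 (SE 0.10, adjusted p = 3.88e-04). Of 12 NF-kB pathway genes 3 rose and 1 fell, by all genes or over the list alone (median 0.18, adjusted p = 0.0192, and 0.243 with an estimated correlation), among them Relb (0.44, SE 0.10, adjusted p = 0.00976). In the WT for Fezf2 against the WT for Aire the NF-kB list had a median of -0.32 (camera adjusted p = 0.00782). That difference between WT groups was larger than the rise here. The MHC class II list had -0.22 between the WT groups (camera adjusted p = 0.00999). Fezf2 itself stood at 626 ± 80.1 CPM in the WT and 874 ± 176 CPM in the libraries labelled Aire KO (0.48, SE 0.15, adjusted p = 0.0413). That call was lost without WT for Aire A (0.50, adjusted p = 0.0935) or B (0.39, 0.154) and without Aire KO B (0.51, 0.0912) or C (0.33, 0.118), with adjusted p from 3.3e-04 to 0.16 over its settings.

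The Fezf2-dependent examples had 5 lower and 1 higher of 9 without passing as a list, by all genes or over the list alone (adjusted p = 0.059). Fabp9, a testis fatty acid-binding protein, went from 118 ± 45.1 to 52.9 ± 4.88 CPM. Of 11 mTEC-lo genes 5 fell (adjusted p = 0.072; 6 lower and 1 higher over the list alone), including Krt5 (-0.69, SE 0.13, adjusted p = 0.00245), a basal keratin. Among 11 neuroendocrine genes 3 fell (adjusted p = 0.173; 4 lower and 2 higher over the list alone), led by the granin Scg2 (-4.46, SE 0.47, adjusted p = 3.78e-05). Among 10 cortical TEC genes Enpep fell by 2.75 and Tbata rose by 1.11 on the log2 scale (adjusted p = 0.873 for the list), the call on Tbata being lost with DESeq2 (0.0549). The lists for testis, tuft, ciliated, MHC class I, TEC identity, NuRD, Aire partner, cell cycle, immediate-early, thymocyte and B cell genes did not pass, with adjusted p between 0.179 and 0.956 and at most 1 member past the threshold in each direction. Chd4 stood at 38.3 ± 5.90 CPM in the WT and 28.95 ± 6.21 CPM in the libraries labelled Aire KO (-0.40, SE 0.20, adjusted p = 0.206). In all, 18 of 36 lists passed with the preset correlation and 0 with an estimated one by camera, whose lowest adjusted p was 0.0505, while limma's fry passed 18.

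**Figure D2:**
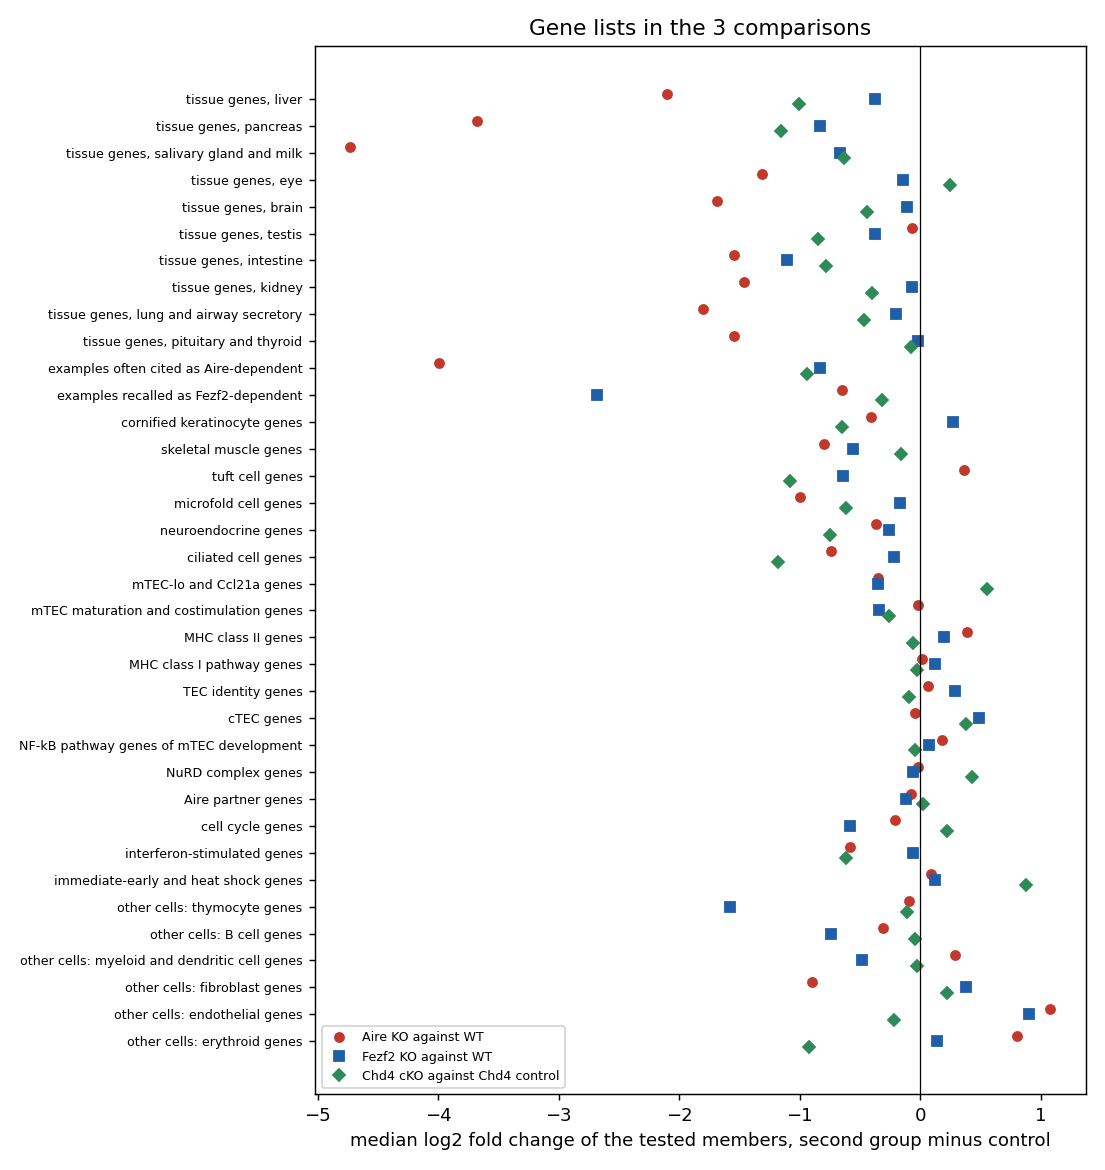
Median log2 fold change of the tested members of each of the 36 gene lists in the 3 comparisons (second group minus control; genes with 0 reads in a group at their bound). The salivary gland and milk list reached -4.73 in the libraries labelled Aire KO and the Fezf2-dependent list -2.68 in the Fezf2 KO.

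The comparison of the Fezf2 KO with its WT asked which mTEC transcripts depend on Fezf2. Every one of the 9 Fezf2-dependent examples fell, among them Krt10, a suprabasal keratin, from 221 ± 54.5 to 31.6 ± 6.43 CPM (log2 fold change -2.80, SE 0.26, adjusted p = 4.94e-04). Intestinal genes were lower as a list, with 6 of 18 past the threshold, a list call lost with an estimated correlation (adjusted p = 0.413). This list was also higher in the WT for Fezf2 than in the WT for Aire (median 0.65, against -1.11 in the Fezf2 KO). Anxa1, annexin A1, was among the genes that rose most, from 399 ± 17.8 to 3789 ± 436 CPM (3.25, SE 0.20, adjusted p = 9.75e-05). Fezf2 went from 652 ± 82.5 to 13.6 ± 8.46 CPM (-5.59, SE 0.41, adjusted p = 1.69e-04). Of 15695 genes tested, 389 were higher and 376 lower, together 4.9%, with median changes of 2.71-fold and 2.82-fold, and 326 and 333 changed at least 2-fold. In 4318 genes (27.5%) the groups did not overlap, where chance gives 10% and the WT for Fezf2 against the WT for Aire gave 20.4%.

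The WT for Fezf2 held more thymocyte transcripts than the Fezf2 KO. The list level, a median over 15 genes, was 5.65, 6.03 and 4.97 log2 CPM in libraries A, B and C of the WT and 3.59, 3.8 and 4.1 in the KO. Of 15 thymocyte genes 8 fell and 0 rose by edgeR (13 and 0 adjusted over the list alone; median -1.58, camera adjusted p = 1.41e-09, and 0.413 with an estimated correlation). Lck, a T cell kinase, went from 116 ± 23.2 to 46.2 ± 4.18 CPM and Dntt, the terminal transferase of immature lymphocytes, from 93.8 ± 29.0 to 30.9 ± 4.2 CPM, with Cd8b1 and Lat also lower (-2.25 and -1.69). None of Lck, Cd8b1, Dntt and Lat passed when Fezf2 KO A, B or C was left out, with adjusted p of at most 0.0738, 0.0712, 0.0764 and 0.115. The list had 12 lower genes without WT library B (median -1.30), 10 without WT library C (-1.82), 4 without WT library A (-1.35) and 0 without Fezf2 KO A (-1.34), B (-1.56) or C (-1.73). Of 10 myeloid and dendritic genes only Fcer1g, an Fc receptor chain, fell, from 72.7 ± 26.7 to 11.2 ± 2.55 CPM (4 lower over the list alone; adjusted p = 0.0209, and 0.413 with an estimated correlation). That list call was lost without WT library A (adjusted p = 0.0593) or B (0.0785), with a range of 0.00758 to 0.413. The myeloid list was also higher in the WT for Fezf2 than in the WT for Aire (median 0.53, against -0.48 in the Fezf2 KO).

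Library B of the WT for Fezf2 stood apart from the rest, with a mean correlation of 0.883 with the other two libraries of its group, where A and C had 0.921 and 0.922. Without it, 1053 genes were higher and 981 lower, and these held 389 of the 389 and 371 of the 376 genes called with all 6 libraries. Leaving out another library gave fewer calls, with 226 higher and 224 lower without WT library A, 266 and 265 without WT library C, 121 and 91 without Fezf2 KO A, 102 and 67 without B, and 119 and 72 without C. DESeq2 called 681 higher and 717 lower.

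Among the genes with the largest increases, F2rl2, a protease-activated receptor, had 2 reads in the WT and 222 in the Fezf2 KO, a ratio of 94.6 with a counting interval of 25.9 to 786. Serpina1e, an alpha-1-antitrypsin, rose from 4.0 ± 1.54 to 88.8 ± 26.6 CPM (4.48, SE 0.34, adjusted p = 1.69e-04). The cornified envelope gene Sprr2a2 rose from 396 ± 153 to 4763 ± 220 CPM (3.59, SE 0.29, adjusted p = 2.29e-04), although near-identical copies such as Sprr2a1 and Sprr2a3 may share its reads. F3, the tissue factor that starts coagulation, rose from 9.64 ± 2.03 to 104 ± 22.0 CPM (3.44, SE 0.26, adjusted p = 1.69e-04), and Tspan7 rose by 3.29 (SE 0.34, adjusted p = 8.86e-04). Btla, an inhibitory lymphocyte receptor, rose by 3.42 (adjusted p = 0.00882), a call lost without Fezf2 KO A (0.0568) or B (0.0555). Sprr2a1 rose by 3.89 (adjusted p = 0.0446), a call lost with DESeq2 (0.343) and without WT library C or any 1 of the 3 Fezf2 KO libraries. Among the lower genes, Pnp2, a purine nucleoside phosphorylase, fell from 26 ± 4.76 to 0.584 ± 0.313 CPM (-5.38, SE 0.43, adjusted p = 2.37e-04). Saa3, an acute-phase protein, fell from 1038 ± 502 to 88.6 ± 18.8 CPM (-3.55, SE 0.35, adjusted p = 7.49e-04), and Pck1, the rate-limiting enzyme of gluconeogenesis, from 82.4 ± 20.9 to 7.70 ± 1.54 CPM (-3.41, SE 0.28, adjusted p = 2.59e-04). Muc3, an intestinal mucin, and Dgkeos, annotated opposite to Dgke and so of uncertain reads, fell by log2 fold changes of -3.43 and -3.92. Hoxc11 fell by 4.16 (adjusted p = 0.0485), a call lost without WT library B (0.072) or without Fezf2 KO A (0.103), B (0.204) or C (0.184).

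The Fezf2-dependent examples had a median of -2.68 (9 lower also over the list alone; camera adjusted p = 1.42e-12, and 0.26 with an estimated correlation). Fabp9 went from 172 ± 92.1 to 13.0 ± 4.75 CPM, the secretory granule protein Resp18 from 166 ± 72.8 to 21.5 ± 5.80 CPM and Apoc3, an apolipoprotein, from 33.9 ± 10.5 to 5.22 ± 0.800 CPM. All 9 were lower without WT library B (median -2.40), 6 without WT library A (-2.83), 7 without WT library C (-2.77), 6 without Fezf2 KO A (-2.79), 5 without B (-2.70) and 5 without C (-2.57). Of 18 intestine genes 6 fell and 0 rose (8 and 0 adjusted over the list alone; median -1.11, adjusted p = 2.47e-05, and 0.413 with an estimated correlation). Vil1, the brush border protein villin, went from 78.4 ± 6.46 to 16.2 ± 4.07 CPM (-2.27, SE 0.24, adjusted p = 0.00108). Apoa4, an intestinal apolipoprotein, went from 430 ± 61.1 to 153 ± 35.6 CPM (adjusted p = 0.00625), a call lost without Fezf2 KO B (0.0627) or C (0.0544). The list had 7 lower genes without WT library B (median -0.87) and 1 each without Fezf2 KO B or C. Of 15 pancreas genes 3 fell and 0 rose, by all genes or over the list alone (median -0.83, adjusted p = 0.00183, and 0.413 with an estimated correlation), with Ins2 from 55.8 ± 22.6 to 15.5 ± 4.0 CPM (adjusted p = 0.0119). The Ins2 call was lost without Fezf2 KO A, B or C (adjusted p of at most 0.0843), and the list call without WT library B (adjusted p = 0.0567, with a range of 3.79e-04 to 0.413). The WT for Fezf2 itself stood above the WT for Aire by medians of 0.25 (Fezf2-dependent), 0.65 (intestine) and 0.83 (pancreas). The pancreas fall was of the size of this difference between WT groups, and the intestine fall was larger. Neither is fully separated from a high level in this control group.

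Of 9 TEC identity genes 2 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.29, adjusted p = 0.0042, and 0.413 with an estimated correlation). Pax9, a transcription factor of the pharyngeal pouch, went from 48.4 ± 5.81 to 98.9 ± 3.12 CPM (adjusted p = 0.0139), and Pax1 had a log2 fold change of 0.89 (adjusted p = 0.039). Pax9 and Pax1 passed in all 6 libraries and without WT library B, and did not pass without any other 1 of the 6 (adjusted p of at most 0.093 and 0.175), and Pax1 was also lost after thinning to equal depth. Of 18 cell cycle genes Mki67, a proliferation marker, fell from 50.3 ± 8.22 to 21.1 ± 5.89 CPM (1 lower also over the list alone; median -0.58, adjusted p = 1.51e-04, and 0.413 with an estimated correlation). The Mki67 call was lost without WT library A (0.0622) or without Fezf2 KO A (0.136), B (0.0515) or C (0.132). Of 17 tuft cell genes 0 passed over all genes by edgeR and 7 were lower over the list alone (median -0.63, adjusted p = 7.12e-04, and 0.451 with an estimated correlation). Their smallest adjusted p were 0.0645 for Ltc4s, 0.0797 for Sh2d6 and 0.0805 for Dclk1. The tuft level was 5.61 ± 0.31 log2 CPM in the WT for Fezf2, 5.05 ± 0.30 in the Fezf2 KO and 4.68 ± 0.47 in the WT for Aire, so the KO stood above the other WT group. The Aire-dependent examples had 2 lower of 9 (3 over the list alone; median -0.83, adjusted p = 0.0042, and 0.413 with an estimated correlation), a call lost without WT library B (adjusted p = 0.0785, with a range of 0.00305 to 0.413). Of 11 salivary gland and milk genes 1 fell, also over the list alone (adjusted p = 0.0343, and 0.413 with an estimated correlation), a list call lost without WT library A (0.0563), WT library B (0.109) or Fezf2 KO C (0.0531), with a range of 0.0236 to 0.413. The WT for Fezf2 stood above the WT for Aire by a median of 0.77 for the Aire-dependent examples, against -0.83 in the Fezf2 KO. For the salivary gland and milk genes these medians were 0.85 and -0.67. Both falls are therefore not separated from a high level in this control group.

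Among the keratinocyte genes members moved both ways, with 4 higher and 2 lower of 17 (5 and 2 adjusted over the list alone; adjusted p = 0.408). Krt1 fell from 72.1 ± 14.5 to 19.0 ± 0.636 CPM (-1.92, SE 0.22, adjusted p = 0.00168), and Sbsn, suprabasin, had 90.7 ± 43.0 and 298 ± 6.96 CPM (adjusted p = 0.0132, and at most 0.0766 without Fezf2 KO A, B or C, where the call was lost). Among 19 liver genes 1 rose and 3 fell (2 and 5 over the list alone; adjusted p = 0.173), with Trf, transferrin, falling from 281 ± 26.8 to 86.1 ± 23.5 CPM (-1.71, SE 0.23, adjusted p = 0.00359). Of 11 lung genes 2 rose and 1 fell (4 and 3 over the list alone; adjusted p = 0.831), and of 12 mTEC maturation genes 4 fell, Fezf2 among them, and 0 rose (5 and 1 over the list alone; adjusted p = 0.0599). The lists for eye, brain, testis, kidney, pituitary, muscle, microfold, neuroendocrine, ciliated, mTEC-lo, MHC class I and II, cortical TEC, NF-kB, NuRD, Aire partner, interferon-stimulated, immediate-early, B cell, fibroblast, endothelial and erythroid genes did not pass, with adjusted p between 0.0684 and 0.99 and at most 2 members past the threshold in each direction. Aire stood at 1209 ± 108 CPM in the WT and 942 ± 122 CPM in the Fezf2 KO (-0.36, SE 0.19, adjusted p = 0.337). Chd4 stood at 71.1 ± 49.3 and 31.9 ± 6.01 CPM (-1.15, SE 0.41, adjusted p = 0.153), with 128.1 CPM in WT library B against 41.72 and 43.58 CPM in A and C. Genes detected at equal depth numbered 21367 ± 319 in the WT and 21271 ± 188 in the KO, a difference of -95.3 (exact two-sided permutation p = 0.6). Counting genes with at least 3 or at least 10 reads, the differences were -353 and -356.7 (exact permutation p = 0.1 for both, the smallest that 3 against 3 can give). In all, 10 of 36 lists passed, 0 by camera with an estimated correlation and 6 by fry. The WT for Fezf2 against the WT for Aire passed more lists by camera with the preset correlation, and as many by fry.

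**Figure D3:**
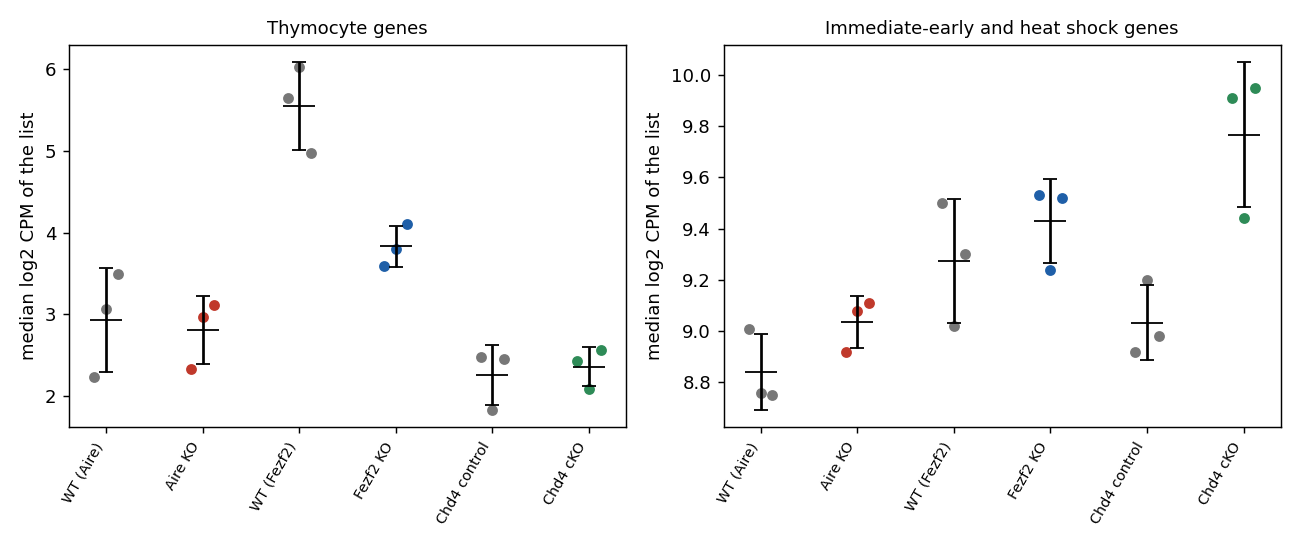
Median log2 CPM of the thymocyte list and of the immediate-early and heat shock list in each of the 18 libraries (points), with the mean and SD of each group of 3 (bars). The thymocyte level was between 4.97 and 6.03 in the WT for Fezf2 and between 1.83 and 4.1 in the other 15 libraries.

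The comparison of the Chd4 cKO with its control asked which mTEC transcripts depend on Chd4. The change was broad and nearly balanced in direction, with tuft, liver, intestine and interferon genes lower as lists and immediate-early genes higher. These list calls were lost with an estimated correlation (adjusted p = 0.455, 0.151, 0.151, 0.151 and 0.493). Their medians were -1.08, -1.01, -0.78, -0.62 and 0.87. Between the WT groups the same lists had medians of 1.06, 0.63, 0.65, 0.18 and 0.54. The tuft shift was thus of the size of a difference between WT groups, and the others were larger. List medians alone do not fully separate these shifts from other differences between groups. Ptgs1, a cyclooxygenase on the tuft cell list, fell from 34.3 ± 4.54 to 11 ± 0.643 CPM (log2 fold change -1.63, SE 0.17, adjusted p = 8.52e-05), and Egr1, an immediate-early transcription factor, rose from 589 ± 58.3 to 1208 ± 309 CPM (1.03, SE 0.17, adjusted p = 0.00124). Chd4 went from 60.3 ± 5.69 to 27.4 ± 2.80 CPM (-1.14, SE 0.13, adjusted p = 1.59e-04). Fezf2 rose from 592 ± 58.3 to 919.9 ± 53.6 CPM (0.64, SE 0.09, adjusted p = 6.55e-04), and Aire fell from 1033 ± 14.5 to 787 ± 34.8 CPM (-0.39, SE 0.07, adjusted p = 0.00294). With all 18 libraries in one fit neither of these last calls was kept, at 0.68 (adjusted p = 0.055) for Fezf2 and -0.35 (adjusted p = 0.0696) for Aire. That fit shares dispersions over all groups. The biological coefficient of variation was 0.149 in this comparison and 0.279 in that of Fezf2. Whether this cost the calls was not tested. Of 15182 genes tested, 2164 were higher and 2175 lower, together 28.6%, with median changes of 1.69-fold and 1.96-fold, and 727 and 1040 changed at least 2-fold. In 6721 genes (44.3%) the groups did not overlap, where chance gives 10% and the WT for Fezf2 against the WT for Aire gave 20.4%. At equal depth 17989.7 ± 168 genes were detected in the cKO and 18503 ± 66.1 in the control, a difference of -513.3 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give).

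The largest increases included Snhg11, a small nucleolar RNA host gene, from 12.1 ± 4.11 to 315 ± 77.9 CPM (4.70, SE 0.25, adjusted p = 2.26e-06), and the apolipoprotein gene Apoc1 from 20 ± 2.23 to 222 ± 20.5 CPM (3.46, SE 0.12, adjusted p = 3.64e-07). Tnnc2, the troponin C of fast muscle, rose from 2.32 ± 1.27 to 28.1 ± 8.23 CPM (3.62, SE 0.37, adjusted p = 8.21e-05), and Tcfl5 from 2.87 ± 0.302 to 34.9 ± 4.58 CPM (3.58, SE 0.22, adjusted p = 5.16e-06). H1fx, a linker histone, Prss41, a serine protease, and Pnck, a calmodulin kinase, rose by log2 fold changes of 3.96, 3.44 and 3.31. Xlr3a, which has near-identical copies, rose by 3.61. The largest decreases included Ccr4, a chemokine receptor, from 56.4 ± 9.35 to 6.36 ± 2.50 CPM (-3.19, SE 0.25, adjusted p = 1.63e-05), and Crisp3, a secretory protein, from 15.5 ± 4.06 to 1.04 ± 0.462 CPM (-3.92, SE 0.38, adjusted p = 6.45e-05). Scgb3a2, an airway secretoglobin, fell from 9.91 ± 5.57 to 0.546 ± 0.272 CPM (-4.34, SE 0.60, adjusted p = 5.51e-04), and Tulp2 from 24.4 ± 2.56 to 1.74 ± 0.943 CPM (-3.68, SE 0.34, adjusted p = 4.31e-05). Zscan4c, Brinp1 and Mgat4c fell by -3.69, -3.38 and -3.21 on the log2 scale.

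All 12 immediate-early and heat shock genes rose, also over the list alone (median 0.87, camera adjusted p = 1.43e-05, and 0.493 with an estimated correlation). Fos went from 558 ± 74.2 to 1288 ± 386 CPM and Jun from 734 ± 23.6 to 1349 ± 388 CPM, transcription factors that cells induce within minutes of a stimulus. Nr4a1 went from 30.2 ± 4.97 to 117 ± 67.7 CPM (1.95, SE 0.36, adjusted p = 0.00296). Of 17 tuft cell genes 12 fell and 0 rose (13 and 0 adjusted over the list alone; median -1.08, adjusted p = 4.27e-06, and 0.455 with an estimated correlation). Besides Ptgs1, these included Alox5ap, the activating protein of 5-lipoxygenase, from 28.9 ± 10.1 to 2.13 ± 1.45 CPM, and Sh2d6 from 35.9 ± 11 to 8.74 ± 2.01 CPM. Of 8 microfold cell genes 4 fell and 0 rose, by all genes or over the list alone (median -0.62, adjusted p = 0.00349, and 0.341 with an estimated correlation), with Ccl20 going from 282 ± 34.7 to 73.7 ± 8.04 CPM and the chemokine Ccl6 from 151 ± 14.9 to 26.4 ± 7.02 CPM. Of 12 ciliated cell genes 7 fell and 1 rose (9 and 1 over the list alone; median -1.18, adjusted p = 0.0114, and 0.341 with an estimated correlation), including the axonemal dynein Dnah5 (-1.52, SE 0.20, adjusted p = 4.22e-04), while Dnah9 rose by 0.72. Of 16 keratinocyte genes 6 fell and 1 rose (9 and 2 over the list alone, median -0.65, adjusted p = 0.00312, and 0.532 with an estimated correlation), with Krtdap from 206 ± 50.1 to 73.5 ± 17.5 CPM and Krt77 from 92.5 to 42.5 CPM. Between the WT groups the ciliated and the keratinocyte lists each had a median of 0.88, larger than the keratinocyte fall here.

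Several tissue lists were lower. Of 19 liver genes 11 fell and 1 rose (12 and 1 adjusted over the list alone; median -1.01, adjusted p = 1.55e-04), with Ttr, transthyretin, going from 33.4 ± 5.94 to 3.43 ± 2.48 CPM. Of 18 intestine genes 11 fell and 1 rose, by all genes or over the list alone (median -0.78, adjusted p = 1.93e-04), with Fabp1, a fatty acid-binding protein, going from 42.3 ± 4.72 to 10.7 ± 0.896 CPM and the crypt marker Olfm4 from 91.5 to 173 CPM. Of 15 pancreas genes 9 fell and 1 rose (11 and 2 over the list alone; median -1.16, adjusted p = 4.77e-04). Iapp, the islet peptide amylin, went from 211 ± 34.8 to 57.8 ± 5.91 CPM and Reg1, a pancreatic stone protein, from 56.6 ± 7.88 to 299 ± 101 CPM. Of 10 Aire-dependent examples 6 fell and 0 rose (8 and 0 over the list alone; median -0.94, adjusted p = 1.55e-04), with the casein Csn2 going from 981 ± 85.2 to 542 ± 68.2 CPM and Ins2 from 31.6 ± 4.49 to 14.1 ± 0.357 CPM. These 4 lists had adjusted p = 0.151 with an estimated correlation. Between the WT groups their medians were 0.63 (liver), 0.65 (intestine), 0.83 (pancreas) and 0.77 (Aire-dependent), each smaller in size than here. The Aire-dependent list was chosen from general knowledge, and 1 of its 9 members tested in the libraries labelled Aire KO rose there. A fall of a member here is therefore not by itself a loss shared with those libraries. Of 16 interferon-stimulated genes 10 fell and 0 rose, by all genes or over the list alone (median -0.62, adjusted p = 6.99e-05, and 0.151 with an estimated correlation), with the transcription factor Irf7 going from 257 ± 20.1 to 125 ± 9.95 CPM. Of 11 salivary gland and milk genes 3 fell and 0 rose (6 and 0 over the list alone; adjusted p = 0.037, and 0.341 with an estimated correlation), a list call lost without Chd4 control B (adjusted p = 0.0663, with a range of 0.00759 to 0.341). Of 5 erythroid genes 3 fell and 0 rose (4 and 0 over the list alone, median -0.92, adjusted p = 0.0114, and 0.487 with an estimated correlation), including Alas2, a haem synthesis enzyme (-0.84, SE 0.15, adjusted p = 0.00246). The salivary gland and milk list had a median of -0.63 here and 0.85 between the WT groups. For the erythroid list the median between the WT groups was -0.94. Neither fall exceeded the difference between WT groups in size.

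Immature mTEC genes were higher as a list, with 7 of 11 mTEC-lo genes higher and 2 lower (8 and 3 adjusted over the list alone; median 0.55, adjusted p = 0.0142, and 0.493 with an estimated correlation). Ccl21a, a chemokine of immature mTECs, rose from 1846 ± 279.6 to 4741 ± 675 CPM, Bcam from 44.2 ± 4.22 to 103 ± 1.66 CPM and the integrin Itgb4 from 153 ± 3.73 to 300.2 ± 14.5 CPM, and Ly6a fell from 528 to 309 CPM. Of 12 mTEC maturation genes 2 rose and 5 fell (3 and 6 over the list alone; adjusted p = 0.248), with Hdc from 1448 ± 116 to 521 ± 82.4 CPM and the costimulatory Cd86 from 46.7 to 14.8 CPM, while Ccl19 rose from 547 ± 33.7 to 1171 ± 139 CPM. Of 9 Fezf2-dependent examples 3 rose and 3 fell, by all genes or over the list alone (adjusted p = 0.898), with Calb1 rising from 30.3 ± 3.93 to 159 ± 41.1 CPM.

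Muscle and other tissue genes moved both ways. Of 14 muscle genes 3 rose and 2 fell (3 and 3 over the list alone; adjusted p = 0.898), with desmin, Des, rising from 40.2 ± 3.54 to 225 ± 18.3 CPM and Myh3 falling by a log2 fold change of -1.31. Of 10 cortical TEC genes 3 rose and 1 fell (adjusted p = 0.355), among them Il7, a cytokine for thymocytes, from 131 ± 22.7 to 283 ± 22.2 CPM. Of 11 lung genes 2 rose and 4 fell (adjusted p = 0.369), with the protease Napsa rising from 62.5 to 161 CPM, and of 7 kidney genes 1 rose and 3 fell (adjusted p = 0.439), with Umod, uromodulin, rising from 16.9 ± 5.49 to 109 ± 29.7 CPM. Pomc fell from 118 ± 15.4 to 41.1 ± 0.128 CPM in a pituitary list of 9 with 1 higher and 2 lower (adjusted p = 0.439). Brain (3 higher, 5 lower of 13; adjusted p = 0.457), eye (3 and 1 of 9; 0.642), testis (1 and 3 of 7; 0.355) and neuroendocrine genes (2 and 5 of 11; 0.369) did not pass as lists. MHC class II (2 and 3 of 11; adjusted p = 0.724) and TEC identity genes (2 and 3 of 10; 0.717) moved both ways, with Ctss, a class II cathepsin, falling from 216 ± 7.39 to 103 ± 6.04 CPM. Of 15 NuRD genes 7 rose and 2 fell, Chd4 among them (8 and 2 over the list alone; adjusted p = 0.0728), with the subunit Gatad2a going from 74.8 ± 3.27 to 130 ± 6.40 CPM. Of 18 cell cycle genes 6 rose and 1 fell, by all genes or over the list alone (adjusted p = 0.0885), with Rrm2, a ribonucleotide reductase subunit, going from 39.9 to 74.2 CPM. Of 12 NF-kB pathway genes 2 rose and 1 fell (adjusted p = 0.898), with Nfkb2 going from 512 to 363 CPM. The MHC class I, Aire partner, thymocyte, B cell, myeloid and fibroblast lists had adjusted p between 0.438 and 0.816 and at most 2 members past the threshold in each direction, and the endothelial list had only 2 tested genes and no test. In all, 13 lists passed, 0 by camera with an estimated correlation and 20 by fry.

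The WT for Fezf2 and the WT for Aire carry the same genotype and strain in the labels, so their comparison served as a background. By edgeR 15 genes were higher and 5 lower of 15656 in the WT for Fezf2, with 1870 at an unadjusted p under 0.05 and 283 higher and 150 lower by DESeq2. In 3199 genes (20.4%) the groups did not overlap, where chance gives 10%. The higher genes included the thymocyte genes Dntt, from 9.72 ± 4.08 to 94.6 ± 29.2 CPM (adjusted p = 0.0317), Lck, from 27.8 ± 9.05 to 116 ± 23.2 CPM (adjusted p = 0.0406), and Cd8a, from 6.88 to 65.2 CPM (adjusted p = 0.0406). None of Dntt, Lck and Cd8a passed without WT for Aire A, B or C or without WT for Fezf2 A, or with sex as a covariate, where their adjusted p were highest (0.512, 0.524 and 0.558). The median of the thymocyte list nevertheless stayed between 2.02 and 2.75 on leaving out a library and was 2.32 with sex as a covariate. The thymocyte list had 4 higher genes of 15, and 14 adjusted over the list alone (median 2.38, adjusted p = 2.26e-21, and 0.189 with an estimated correlation). The tuft list had 0 and 13 (median 1.06, adjusted p = 2.35e-12, and 0.189 with an estimated correlation). The lower genes included the Y-linked helicase Ddx3y, with 643 reads in the WT for Aire and 2 in the WT for Fezf2, a ratio of 302 with a counting interval of 83.3 to 2500, a call on Ddx3y lost without WT for Aire A or C or WT for Fezf2 A or C, with sample quality weights and with sex as a covariate, where its adjusted p was highest (0.512). From Y-linked genes, all 6 libraries of the Fezf2 comparison were called female, as were library B of the WT for Aire and 1 library labelled Aire KO. All 3 Chd4 cKO libraries and 2 Chd4 control libraries were also called female. Chd4 control A was called male, so sex was not balanced between the Chd4 groups. The call for library B of the WT for Aire is less sure, with 12.6 CPM of Y-linked genes where the other libraries called female had at most 1.6, and the sex covariate rests on it. With inferred sex as a covariate 0 genes passed by edgeR, and leaving out a library gave between 0 and 312 higher and between 0 and 324 lower genes, the highest counts without WT for Fezf2 B. Without WT for Aire A or WT for Fezf2 A neither direction held a gene. Without WT for Aire B there were 1 higher and 3 lower, without WT for Aire C 0 and 2, and without WT for Fezf2 C 14 and 0. Aire stood at 2107 ± 264.5 CPM in the WT for Aire and 1219 ± 109 CPM in the WT for Fezf2 (-0.79, SE 0.19, adjusted p = 0.131). Past the threshold in all were 18 lists, 0 by camera with an estimated correlation and 6 by fry. Besides thymocyte and tuft, these were the liver, pancreas, salivary, intestine, lung, pituitary, Aire-dependent, Fezf2-dependent, keratinocyte, ciliated, immediate-early and myeloid lists, higher in the WT for Fezf2 (adjusted p from 8.66e-07 for pancreas to 0.0477). The mTEC maturation, MHC class II, NF-kB and erythroid lists were lower (adjusted p from 3.14e-04 to 0.0111). With the preset correlation as many lists passed for the libraries labelled Aire KO (18), and fewer for the Fezf2 KO (10) and the Chd4 cKO (13). That count therefore does not by itself separate a genotype effect from other differences between groups. By fry the Aire and Chd4 comparisons passed more lists than the WT groups. Fry asks whether the genes of a list changed at all, while camera sets them against the other genes. The biological coefficient of variation was also lower for Aire (0.183) and Chd4 (0.149) than for the WT groups (0.28). The fry count therefore does not by itself separate a genotype effect either. Column names give both WT groups the same sequencing run, and any difference in how they were collected is confounded with the group.

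Genes that fell in one genotype were shared with another more often than independent lists would give. Between the Chd4 cKO and the libraries labelled Aire KO, 471 genes were lower in both, where 191.3 were expected among 13935 genes tested in both (ratio 2.46, one-sided Fisher's exact test adjusted p = 1.54e-91). Pomc (-1.52 and -4.00), the neuropeptide gene Nts (-1.49 and -6.80), Igfbp6 (-1.64 and -3.16), Iapp (-1.87 and -1.86) and Ccl20 (-1.93 and -1.62) were among them. Between the Chd4 cKO and the Fezf2 KO, 119 were lower in both, where 51.1 were expected among 14509 (ratio 2.33, Fisher's exact adjusted p = 1.07e-19), with Pck1 (-1.21 and -3.41), Lyz1 (-1.88 and -1.67), Aoc1 (-0.84 and -2.12), Lgals4 (-1.54 and -1.67) and Smtnl1 (-2.16 and -1.85). Between the Fezf2 KO and the libraries labelled Aire KO, 98 were lower in both, where 35.2 were expected among 14529 (ratio 2.78, Fisher's exact adjusted p = 7.38e-21), with Igf1 (-2.60 and -1.76), Saa3 (-3.55 and -2.46), Vnn3 (-2.31 and -1.89) and Apoc2 (-2.17 and -1.14). Genes higher in both numbered 113 for Chd4 and Aire (112.5 expected, Fisher's exact adjusted p = 0.54), 64 for Chd4 and Fezf2 (51.2 expected, 0.039) and 32 for Fezf2 and Aire (20.3 expected, 0.0113). Msln, mesothelin, rose by 1.43 in the Chd4 cKO and from 457 ± 87.9 to 3475 ± 280.2 CPM in the Fezf2 KO. Overlaps in opposite directions, added after the files were examined, were also above expectation for some pairs, so the excess was not confined to a shared direction. The ratio was 2.12 for genes higher in the Fezf2 KO and lower in the libraries labelled Aire KO, 1.81 for genes lower in the Chd4 cKO and higher in the libraries labelled Aire KO, and 1.76 for genes lower in the Chd4 cKO and higher in the Fezf2 KO. In all 3 comparisons 40 genes were lower and 9 higher. Genes are not independent replicates, so these p values describe these gene sets. Across genes the fold changes correlated weakly, with Pearson's r of 0.22 for Chd4 and Aire, 0.044 for Fezf2 and Aire and 0.015 for Chd4 and Fezf2, and Spearman's rho of 0.039, 0.03 and 0.006.

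The effects of the genotypes were also tested against each other in one fit of 16169 genes. The Chd4 effect was higher than the Fezf2 effect for 1298 genes and lower for 1111. Igf1, a growth factor, had 1.26 in the Chd4 cKO against -2.60 in the Fezf2 KO (difference 3.86, SE 0.26, adjusted p = 7.24e-09), and Des had 2.52 against -1.24 (3.76, SE 0.32, adjusted p = 1.9e-07). Anxa1 had -0.31 against 3.25 (-3.56, SE 0.24, adjusted p = 7.24e-09), and Arg1, arginase, -1.12 against 2.29 (-3.41, SE 0.27, adjusted p = 6.96e-08). The Chd4 effect was higher than the effect of the label Aire KO for 1838 genes and lower for 826. Mpo, the peroxidase of neutrophils, had 0.88 against -6.72 (7.59, SE 0.42, adjusted p = 4.14e-10), and Atp2a1, the calcium pump of fast muscle, 3.15 against -1.57 (4.72, SE 0.32, adjusted p = 7.83e-09). Tulp2 had -3.63 against 1.42 (-5.05, SE 0.35, adjusted p = 1.29e-08). The Fezf2 effect was higher than that of the label Aire KO for 1849 genes and lower for 891, with Psca at 1.74 against -5.33 (7.08, SE 0.33, adjusted p = 2.13e-11). Col14a1, a collagen, differed by -2.15 (SE 0.20, adjusted p = 2.87e-07). Without library B of the WT for Fezf2 the counts were 3057, 3786 and 3143 genes for Chd4 minus Fezf2, Chd4 minus Aire and Fezf2 minus Aire. Chd4 minus Aire uses no Fezf2 library. Its count could change only through what the fit shares over all libraries, that is the filter, the normalization and the dispersions.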

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

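Values for named genes that an alternative fit could test mostly kept their direction and their side of the threshold. All 472 did with RLE. With DESeq2 419 did, 46 passed only then and 7 no longer passed, and with no filter the counts were 419, 50 and 3. With all 18 libraries they were 363, 43 and 32, with sample quality weights 373, 61 and 8, and after thinning 434, 1 and 5. With the filter at 1 CPM 440 stayed and 2 were lost, and with sex as a covariate 333 stayed and 23 were lost. On leaving out a library 2342 stayed, 286 were lost, 53 passed only then and 1 reversed, Fabp9 between the WT groups, which had 0.50 with all 6 and from -0.04 to 0.84. Of 143 list results 143 stayed with RLE, 132 with no filter, 112 with fry and 84 with an estimated correlation, where the other 59 were lost. The cause was not tested for any change in this part unless stated.

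A fold threshold and a missing filter change by construction which genes are counted. The 856 higher genes for Aire became 186 at 2-fold, and the 1401 lower 2257 with no filter. For Chd4 the 2164 higher became 727 at 2-fold and 1179 with all 18 libraries, and the 2175 lower 1040 and 1196. For Fezf2 the 389 higher became 681 with DESeq2, 663 with no filter, 1011 with all 18 libraries and 1193 with quality weights, and between 102 and 1053 on leaving out a library. The 376 lower became 717, 724, 1158 and 1307, and between 67 and 981. Between the WT groups the 15 higher became 283, 313, 342 and 449, 0 with sex as a covariate, and between 0 and 312 on leaving out a library, and the 5 lower 150, 142, 290, 330, 0, and between 0 and 324.

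With an estimated correlation 0 lists passed in each comparison, from 18 for Aire, 13 for Chd4, 10 for Fezf2 and 18 for the WT groups. With fry 20 passed for Chd4, 6 for Fezf2 and 6 for the WT groups. Leaving out a library gave 8 to 16 for Fezf2. The correlation of Chd4 and Aire fold changes went from 0.22 to 0.157 at a level of at least 2 log2 CPM. The ratio of genes higher in Chd4 and Aire went from 1.0 to 0.89 at an adjusted p of 0.01 and to 1.46 at 2-fold. For genes higher in both it lay between 1.13 and 2.05 for Chd4 and Fezf2, the highest at an adjusted p of 0.01, and between 1.5 and 2.19 for Fezf2 and Aire. Over all settings the ratio of genes lower in both to those expected lay between 2.54 and 4.57 for Chd4 and Aire, where it was 2.46 as reported. It lay between 1.87 and 3.57 for Chd4 and Fezf2 and between 2.15 and 3.77 for Fezf2 and Aire. The fall in genes detected for Aire went from -2467 to -1479 at 10 reads, and for Fezf2 from -95.3 to -353 at 3 reads, to -356.7 at 10 reads and to between -275.7 and 26.3 on leaving out a library.

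Among the targeted genes, Aire in the Chd4 cKO had -0.35 (adjusted p = 0.0696) and Fezf2 0.68 (0.055) with all 18 libraries. Aire in the Fezf2 KO had -0.38 (0.0466) with quality weights, and between -0.44 and -0.25 on leaving out a library. Chd4 in the Fezf2 KO had -1.12 (0.0105) with no filter and -1.16 (0.0158) with all 18 libraries. Fezf2 in the libraries labelled Aire KO had 0.50 (0.16) with all 18 libraries, and between 0.33 and 0.62 on leaving out a library. Between the WT groups Aire had -0.80 (0.00463) with DESeq2, -0.81 (0.0449) with no filter, -0.80 (0.00211) with all 18 libraries, -0.72 (0.00454) with quality weights, and between -0.87 and -0.69 on leaving out a library. Fezf2 between the WT groups, 0.01, had -0.01 with no filter, 0.0 with the filter at 1 CPM, -0.08 with quality weights, and between -0.09 and 0.09 on leaving out a library.

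No paired analysis was possible because the columns carry no replicate numbers, so the planned replicate block was not run. The pseudocount alternatives were not run because the tables hold counts, and the sex covariate was not run for Fezf2 because all 6 of its libraries are female. Quality weights, thinning, and leaving out libraries for lists were chosen after seeing the data. At 3571570 to 17220157 exon reads per library, a gene at 0 reads could stand at up to 0.84 CPM in the shallowest library.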

Other observations

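Genes of other cell types also differed. In the libraries labelled Aire KO 1 of 6 endothelial genes was higher, and 4 adjusted over the list alone (median 1.08, adjusted p = 0.00664, and 0.212 with an estimated correlation), with Pecam1 going from 8.05 ± 0.694 to 21.3 ± 4.49 CPM. Of 5 erythroid genes 2 were higher, and 3 over the list alone (median 0.79, adjusted p = 0.0118, and 0.36 with an estimated correlation), a list call lost without WT for Aire A (adjusted p = 0.0518). Between the WT groups the erythroid list had a median of -0.94, larger in size. Fibroblast genes split, with 2 higher and 4 lower of 6 (adjusted p = 0.405). Dcn, decorin, rose from 124 ± 23.3 to 334 ± 42.2 CPM and Col1a1 fell by a log2 fold change of -2.95 (SE 0.40, adjusted p = 2.53e-04). Of 7 myeloid genes 2 were higher and 1 lower (adjusted p = 0.344), with Csf1r falling by -2.16 (SE 0.32, adjusted p = 5.1e-04). In the Chd4 cKO the fibroblast gene Lum rose by 2.86 (SE 0.23, adjusted p = 2.07e-05) and Lyz2 fell by -0.92 (SE 0.12, adjusted p = 4.54e-04).

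Overlaps in opposite directions were counted only after the files were examined. Of the genes lower in the Chd4 cKO, 201 were higher in the libraries labelled Aire KO (110.8 expected, Fisher's exact adjusted p = 3.78e-18) and 93 higher in the Fezf2 KO (52.8 expected, 3.12e-08). Of the genes higher in the Chd4 cKO, 179 were lower in the libraries labelled Aire KO (194.2 expected, 0.901) and 64 lower in the Fezf2 KO (49.5 expected, 0.0227). Of the genes higher in the Fezf2 KO, 72 were lower in the libraries labelled Aire KO (34 expected, 1.23e-09), and of those lower in the Fezf2 KO 34 were higher (21.1 expected, 0.00703). Gm6768, chosen after its values were seen, had 0 reads in all 3 libraries of the WT for Fezf2 and 122.31, 109.86 and 110.56 CPM in the Fezf2 KO (adjusted p = 8e-05). In the Aire comparison Gm6768 had 76.91, 84.59 and 0 CPM in the WT and 85, 80.81 and 4.26 CPM in the libraries labelled Aire KO (adjusted p = 0.971). A difference in colony background between the Fezf2 groups was not tested, so these values do not separate it from the Fezf2 genotype.

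The tests of the Aire transcript, of cycling mTECs as the source of the thymocyte transcripts and of the gene counts of other splits were chosen only after the result was seen. Thymocyte genes were lower in the Fezf2 KO than in its WT. Thymocyte RNA mainly in library B did not explain this, since the list median was -1.3 without library B. Thymocyte RNA in all 3 WT libraries for Fezf2 is consistent with the list level, whose smallest excess over the mean of the WT for Aire was 2.04 log2 CPM. Cycling mTECs as the source of the thymocyte transcripts did not explain the excess of the WT for Fezf2 over the WT for Aire, which was above the cell cycle excess by 2.72 log2 CPM (spread 0.87). The cell cycle list alone does not separate fewer cycling mTECs from fewer thymocytes in the Fezf2 KO, because it fell there too, with a median of -0.49 without library B. Levels compared after the result was seen did not follow each other between the Fezf2 KO and the WT for Aire. The Fezf2 KO had a lower cell cycle level than the WT for Aire (4.75 ± 0.31 against 5.39 ± 0.23 log2 CPM). Its thymocyte level was higher (3.83 ± 0.26 against 2.93 ± 0.64). The WT for Aire is the control of another comparison, so these levels do not decide what fell between the Fezf2 KO and its own WT. Both cycling mTECs and thymocytes may still have fallen in the Fezf2 KO.

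The Aire transcript was higher in the libraries labelled Aire KO. Swapped labels would make the Aire-dependent examples higher in those libraries, and their median was -3.99, so swapped labels did not explain it. A larger share of mature mTECs cannot be told apart, with a median of -0.08 for the mTEC maturation list without Aire. No other biological explanation was tested.

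Immediate-early and heat shock genes were higher in the Chd4 cKO. Unequal depth of the Chd4 libraries did not explain this, since 12 of the 12 genes were higher with the 6 libraries thinned to equal depth. A single deciding library did not explain it either, with at least 9 genes past the threshold when 1 library was left out. Different handling of the cells before lysis may raise all 12 genes as well, and no label of handling separates it from the genotype, so it cannot be told apart.

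Other splits of the libraries were counted beside the real ones. With 10 splits of 6 libraries a share cannot go under 0.05. Splits with at least the real number of genes past the threshold numbered 1 of 10 for Aire (2257 real, highest other 0), 1 for Fezf2 (765, 3), 1 for Chd4 (4339, 1) and 1 for the WT groups (20, 0). For gene lists they numbered 1 for Aire (18 real, highest other 11), 2 for Fezf2 (10, 13) and 1 for Chd4 (13, 12). For differences of effects 1 of 30 regroupings, the real one itself, reached the real count in each case, 2409 genes for Chd4 minus Fezf2 (highest other 227), 2664 for Chd4 minus Aire (704) and 2740 for Fezf2 minus Aire (905), shares under 0.05. A regrouping shuffles KO and control labels within each comparison, so it stands for no genotype effect at all. It does not stand for equal effects of 2 genotypes. These shares therefore cannot decide whether the effects of 2 genotypes differ.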
